A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

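Total RNA of 8 yeast samples was measured on one-colour oligonucleotide arrays, 1 array per sample, in 4 groups of 2 taken from the labels: untreated wild type, wild type with MMS, untreated sgs1 null and sgs1 null with MMS. The table held 1 intensity per probe set and array, as deposited by the authors, and the values were not on a log scale. The array software, the scaling target and any background correction used to make these intensities are not given in the sources used here. The deposited array means lay between 1906 and 2000, a spread of 4.93%, and the deposited medians were 902.45 and 874.4 for untreated sgs1 null, 878.5 and 971.6 for sgs1 null with MMS, 840.05 and 775 for untreated wild type and 839.75 and 946.65 for wild type with MMS, a spread of 25.4%. How the authors scaled or centred the values stays unknown. With 2 arrays per group, the number of arrays limits the precision.

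The table had 8363 probe sets. The 32 control probe sets and 1 probe set with a missing value were left out, which left 8330. Gene names came from the platform annotation supplied with the data, checked against the RefSeq gene table of assembly R64, and 0 symbols needed updating. Of the probe sets, 6269 had 1 gene symbol, 309 had several and 1752 had none. Probe sets with several or no symbols were tested but never named. Probe sets of the same gene were averaged on the log scale, which concerned 291 genes, and gave 7641 features, of which 5580 were named genes.

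The design, the alternatives, the gene lists and the rule for naming genes were set before the data were examined, apart from the floor described here. Because the array medians differed by more than the 5% set for keeping the deposited scale, the arrays were quantile normalized. The fit departed from the written design in how low values were treated. The design named a floor, the 10th percentile of the positive values after scaling, only for values at or below 0. Of the deposited values, 4 were 0, and after normalization that wording raised none and gave the same calls as no floor. Instead every value below the 10th percentile, 97.1, was raised to it, a reading chosen with the values in hand. The count for MMS in sgs1 null was 192 with this floor and 56 with the written wording, and the other counts under that wording are given in the closing part. Genes at the floor on both arrays of a group have only a bound there, and their fold is given as at least that size. Normalized values were put on the log2 scale and fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes without trend) as group means over all 8 arrays, with 4 residual and 0.986 prior degrees of freedom. The 7 contrasts were tested two-sided, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. All adjusted p-values of genes are limma's.

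The gene lists numbered 35, and 34 of them had at least 5 measured members and were tested with limma's camera at a preset correlation of 0.01, adjusted over lists within each contrast. Of the list calls, 0 held in any contrast with the correlation among members estimated. Camera compares a list with all other genes. The directional test of limma's fry, run as an alternative, tests whether a list's genes move, on balance, one way, and does not compare them with other genes. Genes were named by a fixed rule: per contrast up to 10 with the largest rise and up to 10 with the largest fall among those past the threshold whose groups did not overlap on the arrays, filled up to 5 per direction with the smallest p where fewer passed, 5 per direction for the interaction, up to 4 members per list past the threshold, up to 4 with the largest change of each list that camera called, and a set of damage-response genes with SGS1.

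The steps were tested on simulated data with known answers, drawn from the spread of the real arrays. Errors were drawn independently for each array, and only 50 features per fold size, all above the floor, were changed. The real arrays shared deviations by mark and MMS moved more features, so these rates need not carry over to them. Of the simulated 4-fold changes, 52% were recovered for MMS in wild type, 56% for MMS in sgs1 null, 46% for the strain difference untreated, 50% for it with MMS, 42% for the interaction, 86% for MMS averaged over strains and 70% for the strain difference averaged over treatments. Of the simulated 2-fold changes, 14% were recovered for MMS in wild type, 12% for MMS in sgs1 null, 16% for the strain difference untreated, 2% for it with MMS, 4% for the interaction, 48% for MMS averaged over strains and 40% for the strain difference averaged over treatments. Of the 7641 features, those called without having a simulated change numbered 5, 4, 4, 2, 6, 16 and 7 in the same order of contrasts. In the simulated lists, camera called the shifted list and 0 of the others.

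Alternatives tried were median centring and the deposited scale in place of quantile normalization, a floor at the 20th percentile, an offset of the 25th percentile before log2, leaving out the dimmest 25% or 50% of the features, the brightest probe set per gene, eBayes with trend and robust, array weights, only the 4 arrays of the groups compared, the rep mark of the labels as a block, other thresholds, leaving out each array in turn, and other list tests. Where leaving out an array left a group with 1 array, that array was taken to vary like those of the other groups. Alternatives added after the data were seen are named in the closing part. Signal near the floor limits what can be said of dim genes.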

Results

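The data were 8 one-colour oligonucleotide arrays of total RNA from budding yeast, Saccharomyces cerevisiae, in log phase. They fell into 4 groups of 2 arrays: wild type and an sgs1 null strain, each grown untreated or with methyl methanesulfonate (MMS), an alkylating agent that damages DNA. SGS1 encodes a RecQ-family DNA helicase, a homolog of the helicases lost in the human Werner and Bloom syndromes, and the series was described as a study of yeast ageing. The dose and the time of MMS are not given in the sources used here. The second array of each group carried the word rep in its label. Nothing in the labels says that the arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision. The comparisons were the MMS response in each strain and averaged over strains, the strain difference untreated, with MMS and averaged, and the difference between the MMS responses. Changes are log2 values ± standard error, with p-values adjusted over 7641 features.

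The deleted gene was examined first. The deposited SGS1 intensity in the sgs1 null strain was 1.7 and 2.9 untreated and 17.7 and 2.1 with MMS. In wild type it was 444.2 and 777.3 untreated and 339.1 and 577.3 with MMS, so all 4 arrays of each strain lay on the side of their label. All sgs1 null values were below the floor of 97.1 set on low intensities, which makes the fold a bound. Against that floor SGS1 was at least 6.67-fold lower in the null strain untreated (adjusted p = 0.134), at least 4.53-fold lower with MMS (adjusted p = 0.299) and at least 5.50-fold lower averaged over treatments (adjusted p = 0.0637). None of these passed the threshold of 0.05. With low values left as they were, the literal wording of the design, the average passed (adjusted p = 0.0055), but that fit used null-strain readings below the floor, so its fold is not a measured size. Over the settings tried the adjusted p of this average ran from 0.0055 to 0.414.

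In wild type, many genes changed with MMS. OYE3, an NADPH oxidoreductase of the old yellow enzyme family, rose by 3.48 ± 0.16 (adjusted p = 0.0044), from an intensity of 1057 ± 14.6 (SD, n = 2) to 11798 ± 640 (SD, n = 2). ATR1, a multidrug efflux pump, rose by 3.76 ± 0.15, GPX2, a thiol peroxidase, by 3.55 ± 0.26, and SRX1, which encodes sulfiredoxin, by 2.98 ± 0.27. AAD6, of the aryl-alcohol dehydrogenase family, was at the floor in untreated wild type and was at least 14.7-fold higher with MMS (adjusted p = 0.00959). PHO3, a secreted acid phosphatase, fell by 3.51 ± 0.11 (adjusted p = 0.00267), ANB1, a translation factor expressed under low oxygen, by 4.05 ± 0.38, HEM13, an enzyme of haem synthesis, by 3.76 ± 0.64, and ADH2, the glucose-repressed alcohol dehydrogenase, by 2.88 ± 0.15.

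Among the markers of the DNA damage response in wild type, RAD54, a recombination protein, rose by 1.85 ± 0.18 (adjusted p = 0.0147), DDI1 by 2.05 ± 0.20 and RNR1, the large subunit of ribonucleotide reductase, by 1.42 ± 0.22 (adjusted p = 0.0328). The values of RNR3 (1.99 ± 0.44, adjusted p = 0.0678), of the alkylation repair glycosylase gene MAG1 (1.41 ± 0.33, adjusted p = 0.0756), of RNR4 (0.42 ± 0.11), RNR2 (0.43 ± 0.18), HUG1 (0.52 ± 0.23) and DDR48 (0.30 ± 0.14) did not pass. Other genes with large rises were YLR460C (3.96 ± 0.40), OSI1 (3.29 ± 0.41), YLR108C (3.17 ± 0.33), MRX16 (3.10 ± 0.17) and SDL1 (2.90 ± 0.43). Other large falls were those of SFG1 (-3.08 ± 0.24), CHS2 (-2.99 ± 0.40), TDA6 (-2.75 ± 0.25), WSC4 (-2.72 ± 0.23), NRS1 (-2.71 ± 0.20) and the cell wall mannoprotein gene CWP1 (-2.70 ± 0.49). In all, 485 features passed the threshold, 261 higher and 224 lower, and 388 of them carried a gene name. The balance turned with the scaling, being 237 higher and 309 lower with median centring and 311 and 200 on the deposited scale. Unadjusted p was under 0.05 for 1883 features. The count depended on single arrays: it was 275 without either untreated sgs1 null array, 246 without either MMS-treated sgs1 null array, 4 and 0 without the first and the second untreated wild-type array, and 5 and 6 without the first and the second MMS-treated wild-type array. In the fit with 0, limma gave an unadjusted p under 0.05 for 1342 features. All 485 features kept their direction in each of those 8 fits. Fits without an sgs1 null array could not change a wild-type value. The features were also chosen on these same arrays, so the kept directions are no added support.

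Camera called several gene groups fixed beforehand as higher with MMS in wild type. Of 38 proteasome genes, 14 rose, 0 fell and 24 did not pass, with a median of 0.90. In that list, 32 rose when adjusted over the list alone. Examples were UFD1 (1.65 ± 0.11), which works with CDC48 and is not a subunit, RPT3 (1.59 ± 0.22), PRE1 (1.33 ± 0.23) and RPN9 (1.32 ± 0.19). The list was called by camera (adjusted p = 1.26e-16) but not with the correlation among its members estimated (adjusted p = 0.127 with an estimated correlation). Of 29 genes of oxidative stress and glutathione, 13 rose, 0 fell and 16 did not pass. Adjusted over the list alone, 20 rose and 2 fell (median 0.89, camera adjusted p = 3.66e-09, adjusted p = 0.0689 with an estimated correlation). Of 47 DNA replication genes, 6 rose and 41 did not pass. There were 9 that rose when adjusted over the list alone (median 0.48, camera adjusted p = 5.98e-05, adjusted p = 0.127 with an estimated correlation). Among them were DPB2 (1.36 ± 0.13), ORC3 (1.16 ± 0.13) and RFA1 (1.35 ± 0.12), the large subunit of the single-strand DNA binding complex. Of 18 nucleotide excision repair genes, 4 rose and 14 did not pass. Adjusted over the list alone 9 rose and 1 fell (median 0.64, camera adjusted p = 0.00427, adjusted p = 0.171 with an estimated correlation). SSL2 rose by 1.80 ± 0.23 and RAD4 by 0.98 ± 0.17. Of 18 checkpoint genes, 2 rose and 16 did not pass. A total of 4 rose when adjusted over the list alone (median 0.70, camera adjusted p = 0.0067, adjusted p = 0.171 with an estimated correlation). The checkpoint kinase gene DUN1 rose by 1.17 ± 0.15. Of 19 genes of the iron regulon, 4 rose and 15 did not pass. In that list 7 rose when adjusted over the list alone (median 0.79, camera adjusted p = 0.00168, adjusted p = 0.176 with an estimated correlation). FRE1, a ferric reductase gene, rose by 2.70 ± 0.19. Without the second untreated wild-type array the median was 0.45 for the checkpoint list and 0.51 for the iron regulon.

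Other groups were called lower with MMS in wild type by camera. Of 22 genes of the G2/M transition, 7 fell and 15 did not pass. A total of 10 fell when adjusted over the list alone (median -0.98, camera adjusted p = 8.55e-07, adjusted p = 0.171 with an estimated correlation). They included CHS2, the septum chitin synthase, ALK1 (-1.56 ± 0.17), KIN3 (-1.37 ± 0.13) and SPO12 (-1.28 ± 0.12). Of 36 genes of the respiratory chain and ATP synthase, 3 fell and 33 did not pass. A total of 14 fell when adjusted over the list alone (median -0.61, camera adjusted p = 1.07e-07, adjusted p = 0.126 with an estimated correlation). Among them were CYT1 (-1.54 ± 0.24) and COR1 (-0.67 ± 0.10). Of 24 ergosterol biosynthesis genes, 4 fell and 20 did not pass. A total of 8 fell when adjusted over the list alone (median -0.56, camera adjusted p = 4.99e-06, adjusted p = 0.171 with an estimated correlation). Among them were ERG5 (-1.77 ± 0.19) and MVD1 (-1.48 ± 0.15). Of 26 cell wall genes, 5 fell and 21 did not pass. Adjusted over the list alone 10 fell and 2 rose (median -0.34, camera adjusted p = 0.00893, adjusted p = 0.449 with an estimated correlation). The cell wall call was lost without the first MMS-treated wild-type array (median -0.12, adjusted p = 0.0832), and the median was -0.59 without the first untreated one. The smallest shift was that of the list of cytosolic ribosomal proteins, set by a pattern of names that also took in RPP1, a subunit of RNase P. Of its 81 genes, 1 fell and 80 did not pass, with 0 when adjusted over the list alone (median -0.12, camera adjusted p = 0.0067, adjusted p = 0.528 with an estimated correlation). This call was lost without the second MMS-treated wild-type array (adjusted p = 0.0565). Of 24 citrate cycle genes, 1 fell and 23 did not pass. Adjusted over the list alone 3 fell and 1 rose (median -0.37, camera adjusted p = 0.0495, adjusted p = 0.537 with an estimated correlation). That call was lost without either untreated sgs1 null array (adjusted p = 0.0791 for each), the first or the second untreated wild-type array (adjusted p = 0.0521 and 0.096) or the first MMS-treated wild-type array (adjusted p = 0.253), and without the dimmest 25% of features (adjusted p = 0.0915). Its median was -0.24 without the second untreated and -0.16 and -0.63 without the first and the second MMS-treated wild-type array. Of the 34 lists, camera called 6 higher and 6 lower in wild type.

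In the sgs1 null strain, MMS raised many of the same genes. AAD6 rose by 3.77 ± 0.26, OYE3 by 3.50 ± 0.16 (adjusted p = 0.00796), SRX1 by 3.40 ± 0.27 and YLR460C by 3.23 ± 0.40. GPX2 rose by 2.95 ± 0.26, the glutathione transferase gene GTT2 by 2.73 ± 0.17 and AAD4 by 2.57 ± 0.09 (adjusted p = 0.00386). ATR1 rose by 2.17 ± 0.15 and FRE1 by 2.27 ± 0.19. SNR19 rose by 2.86 ± 0.35, YLR108C by 2.84 ± 0.33 and OSI1 by 2.72 ± 0.41. PHO3 fell by 2.74 ± 0.11 (adjusted p = 0.00605), ANB1 by 2.61 ± 0.38, CYC7, the low-oxygen isoform of cytochrome c, by 2.34 ± 0.28. NRS1 fell by 2.20 ± 0.20, MIN7 by 2.16 ± 0.18 and TDA6 by 2.07 ± 0.25. There were falls too of the maltose transporter gene MAL11 by 1.96 ± 0.27, ADH2 by 1.89 ± 0.15, AAD10 by 1.84 ± 0.19 and the histone gene HTB2 by 1.84 ± 0.27. RAD54 rose by 1.38 ± 0.18 (adjusted p = 0.0358) and DDI1 by 2.14 ± 0.20. RNR1 (1.37 ± 0.22, adjusted p = 0.0535), RNR3 (0.90 ± 0.44), MAG1 (0.97 ± 0.33), RNR2 (0.52 ± 0.18), RNR4 (0.28 ± 0.11), HUG1 (-0.59 ± 0.23) and DDR48 (0.50 ± 0.14) did not pass. In all, 192 features passed, 109 higher and 83 lower, 165 of them named, and unadjusted p was under 0.05 for 1540. With median centring 86 were higher and 89 lower, and on the deposited scale 77 and 66. Without 1 array the count was 13 and 8 for the first and the second untreated sgs1 null array, 1 for either MMS-treated sgs1 null array, 5 for either untreated wild-type array and 4 for either MMS-treated wild-type array. All 192 kept their direction in each of those fits. Leaving out a wild-type array could not change these values, and the features were chosen on the same arrays, so the kept directions are no added support. With low values left as they were, 56 features passed, 52 of them among the 192.

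Of the 38 proteasome genes in the sgs1 null strain, 8 rose and 30 did not pass. A total of 33 rose when adjusted over the list alone (median 0.94, camera adjusted p = 1.27e-18, adjusted p = 0.105 with an estimated correlation). Of the 29 oxidative stress and glutathione genes, 9 rose and 20 did not pass. Adjusted over the list alone 20 rose and 2 fell (median 0.92, camera adjusted p = 1.95e-10, adjusted p = 0.0536 with an estimated correlation). Of the 47 DNA replication genes, 2 rose and 45 did not pass, namely RFA1 (1.59 ± 0.12) and RFA2 (1.36 ± 0.11). Adjusted over the list alone 9 rose and 1 fell (median 0.43, camera adjusted p = 4.69e-05, adjusted p = 0.105 with an estimated correlation). Of the 19 iron regulon genes, 3 rose and 16 did not pass, FRE1, SIT1 (1.97 ± 0.18) and FTR1 (1.17 ± 0.11). A total of 8 rose when adjusted over the list alone (median 0.65, camera adjusted p = 5.57e-05, adjusted p = 0.136 with an estimated correlation), and the median was 1.08 without the first MMS-treated sgs1 null array. None of the 18 nucleotide excision repair genes passed over all genes, and adjusted over the list alone 6 rose and 2 fell (median 0.53, camera adjusted p = 0.00469, adjusted p = 0.191 with an estimated correlation). Of the 36 respiratory chain genes, 3 fell and 33 did not pass, INH1 (-1.77 ± 0.20), QCR10 (-1.37 ± 0.18) and COR1 (-0.86 ± 0.10). A total of 10 fell when adjusted over the list alone (median -0.49, camera adjusted p = 3.94e-09, adjusted p = 0.0913 with an estimated correlation). Of 12 hexose transporter genes, 1 fell, HXT4 (-1.59 ± 0.19), and 11 did not pass, with 4 lower when adjusted over the list alone (median -0.40, camera adjusted p = 0.00161, adjusted p = 0.132 with an estimated correlation). Of the 26 cell wall genes, 2 fell and 24 did not pass, PST1 (-1.62 ± 0.11) and DAN1 (-0.91 ± 0.08). There were 6 that fell when adjusted over the list alone (median -0.45, camera adjusted p = 0.000156, adjusted p = 0.353 with an estimated correlation).

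Other groups were called in the sgs1 null strain with calls that rested on single arrays. Of the 22 G2/M genes, 1 fell, SPO12 (-1.10 ± 0.12), and 2 fell when adjusted over the list alone (median -0.33, camera adjusted p = 0.00203, adjusted p = 0.324 with an estimated correlation). The G2/M call was lost without the first MMS-treated sgs1 null array (adjusted p = 0.122). Of the 24 ergosterol genes, 2 fell, ERG5 (-1.55 ± 0.19) and ERG28 (-1.14 ± 0.10), and 3 fell when adjusted over the list alone (median -0.22, camera adjusted p = 0.0165, adjusted p = 0.353 with an estimated correlation). That call was lost without the first untreated sgs1 null array (adjusted p = 0.0998) or the first MMS-treated sgs1 null array (adjusted p = 0.174), and without the dimmest 25% of features (adjusted p = 0.0676). The lists of ribosome biogenesis (83 genes, median 0.24, camera adjusted p = 0.0293, adjusted p = 0.525 with an estimated correlation) and of ribosomal proteins (median -0.15, with the same adjusted p by both tests) had 0 members past the threshold, over all genes or adjusted over the list alone. Ribosome biogenesis lost its call without the first untreated (adjusted p = 0.256) or the first MMS-treated (adjusted p = 0.339) sgs1 null array. The ribosomal protein call was lost without the first untreated (adjusted p = 0.383) or the second MMS-treated one (adjusted p = 0.559). Without the first and the second MMS-treated sgs1 null array, the medians were -0.20 and -0.64 for G2/M, -0.04 and -0.38 for ergosterol, 0.05 and 0.36 for ribosome biogenesis and -0.24 and 0.0007 for the ribosomal proteins. With the dimmest 25% of features left out, neither ribosomal list was called (adjusted p = 0.0601 for ribosome biogenesis and 0.0721 for the ribosomal proteins). Of the 34 lists, camera called 8 higher and 8 lower in sgs1 null, of which those with calls resting on single arrays are described only in part.

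The MMS responses of the 2 strains share no array and were correlated across the 7641 features (Pearson r = 0.730, Spearman rho = 0.669), with genes not being independent replicates. The correlation was 0.760 within the arrays without the rep mark and 0.555 within those with it. Of the 261 features that rose in wild type and the 109 that rose in the sgs1 null strain, 91 were shared, against 3.72 for independent lists. Of the 224 and 83 that fell, 66 were shared, against 2.43 for independent lists. The lists were not independent, because both tests used the same estimate of each feature's spread, so these expected counts are not a strict baseline. Among the 520 features called in either strain, 507 had the same sign in both strains, and over all features the share with the same sign was 73.7%.

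**Figure D1:**
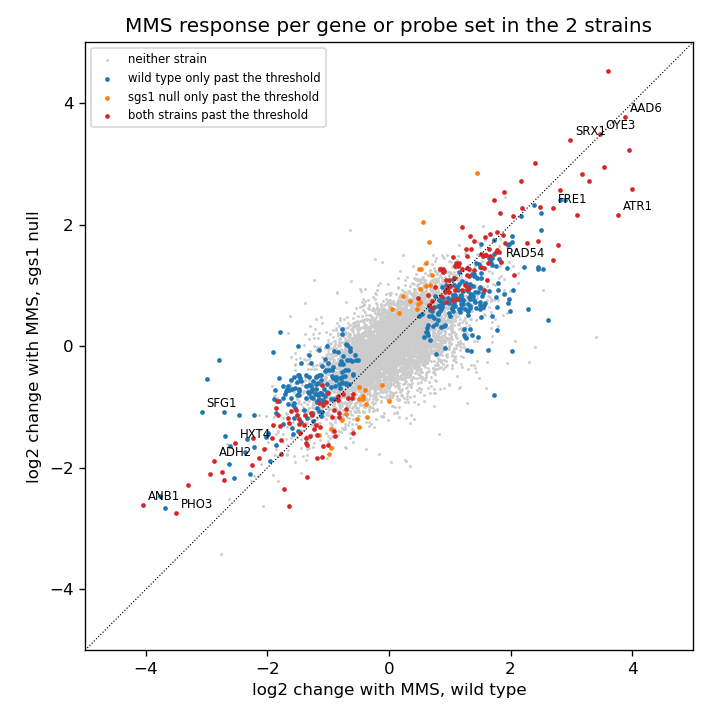
Log2 change with MMS in wild type (horizontal axis) and in the sgs1 null strain (vertical axis) for each of 7641 features, coloured by the strain in which the adjusted p was under 0.05. The points follow the diagonal (r = 0.730), with 91 features higher and 66 lower in both strains.

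Averaged over strains, which sets 4 arrays against 4, RAD54 rose with MMS by 1.62 ± 0.13 (adjusted p = 0.00492), RNR1 by 1.40 ± 0.15 (adjusted p = 0.00923), RNR3 by 1.45 ± 0.31 (adjusted p = 0.0416), RNR4 by 0.35 ± 0.08 (adjusted p = 0.0435), DDI1 by 2.09 ± 0.14 and MAG1 by 1.19 ± 0.23 (adjusted p = 0.0333). RNR2 (0.47 ± 0.13, adjusted p = 0.0748), DDR48 (0.40 ± 0.10, adjusted p = 0.0556) and HUG1 (-0.03 ± 0.16) did not pass. Among the genes with large rises, AAD6 was at least 14.2-fold higher (its untreated wild-type level being at the floor) and OYE3 11.2-fold, GPX2 9.52-fold and SRX1 9.13-fold higher. ANB1 fell by 3.33 ± 0.27, PHO3 by 3.13 ± 0.08 (adjusted p = 0.000565), HEM13 by 3.11 ± 0.45 and SIP18 by 3.09 ± 0.43. The hexose transporter gene HXT4 fell by 2.06 ± 0.14, HTB2 by 1.99 ± 0.19 and TLC1, the RNA component of telomerase, by 1.87 ± 0.14 (adjusted p = 0.00462).

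**Figure D2:**
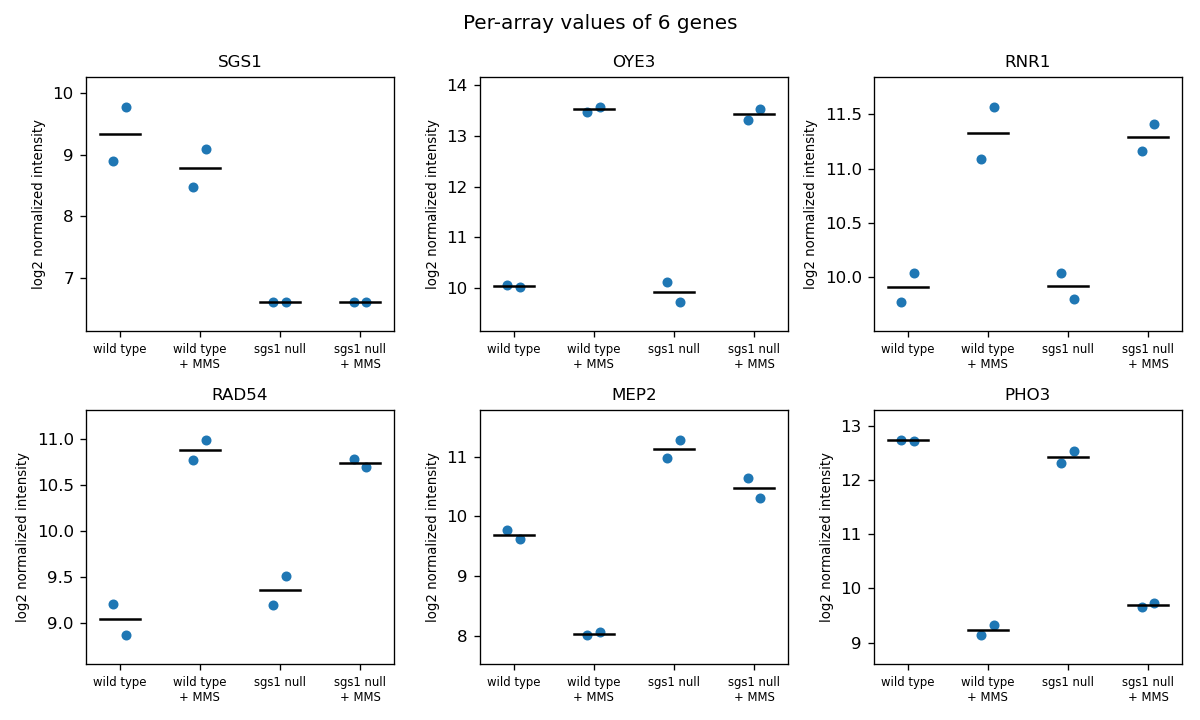
Normalized log2 intensity of 6 genes on each of the 8 arrays, with 1 point per array and the line at the mean of 2. OYE3, RNR1 and RAD54 lay higher and PHO3 lower with MMS in both strains, MEP2 lay higher in the sgs1 null strain, and SGS1 lay at the floor on all 4 arrays of that strain.

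In the average over strains, 30 of 38 proteasome genes rose and 8 did not pass, with 36 higher when adjusted over the list alone (median 0.93, camera adjusted p = 6.45e-18, adjusted p = 0.112 with an estimated correlation). Of the oxidative stress and glutathione genes, 19 of 29 rose and 2 fell (median 0.92, 21 higher and 2 lower when adjusted over the list alone, camera adjusted p = 2.5e-09, adjusted p = 0.0691 with an estimated correlation). Of 47 DNA replication genes, 12 rose and 35 did not pass (median 0.53, 23 higher and 1 lower when adjusted over the list alone, camera adjusted p = 1.79e-05, adjusted p = 0.109 with an estimated correlation). Among them were RFA1 (1.47 ± 0.08), MCM6 (1.40 ± 0.30) and CDC45 (1.27 ± 0.22). Of 18 nucleotide excision repair genes, 7 rose and 1, RAD10, fell (median 0.54, 10 higher and 2 lower when adjusted over the list alone, camera adjusted p = 0.00263, adjusted p = 0.162 with an estimated correlation). Of 18 checkpoint genes, 4 rose (median 0.48, 5 higher when adjusted over the list alone, camera adjusted p = 0.0125, adjusted p = 0.175 with an estimated correlation), while in the sgs1 null strain alone camera did not call this list (0 members past the threshold, 0 when adjusted over the list alone, median 0.27, camera adjusted p = 0.124). Among them were PDS1 (1.28 ± 0.20) and DUN1 (0.87 ± 0.10). Of 19 iron regulon genes, 8 rose (median 0.72, 10 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.000267, adjusted p = 0.162 with an estimated correlation). Among them were FRE1 (2.49 ± 0.13) and TIS11 (2.01 ± 0.30). Camera did not call the lists of homologous recombination (21 genes, 1 higher), base excision and alkylation repair (12 genes, 3 higher and 1 lower) or mismatch repair (6 genes, 2 higher). Nor did it call postreplication repair (10 genes, 2 higher and 1 lower) or ribonucleotide reductase and Crt1 targets (8 genes, 3 higher and 1 lower, adjusted p = 0.113).

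Of 36 respiratory chain genes, 16 fell and 20 did not pass in the average (median -0.52, 22 lower when adjusted over the list alone, camera adjusted p = 2.5e-09, adjusted p = 0.0864 with an estimated correlation). Among them were INH1 (-1.38 ± 0.14), COX4 (-1.32 ± 0.21) and CYT1 (-1.28 ± 0.17). Of 22 G2/M genes, 8 fell (median -0.63, 9 lower when adjusted over the list alone, camera adjusted p = 8.33e-06, adjusted p = 0.162 with an estimated correlation). Of 24 ergosterol genes, 4 fell (median -0.36, 9 lower when adjusted over the list alone, camera adjusted p = 0.000129, adjusted p = 0.175 with an estimated correlation). Of 26 cell wall genes, 8 fell (median -0.37, 10 lower and 2 higher when adjusted over the list alone, camera adjusted p = 0.00202, adjusted p = 0.38 with an estimated correlation). Among them were CWP1 (-2.09 ± 0.35), TIR3 (-2.02 ± 0.27) and TIR1 (-1.76 ± 0.20). Of 12 hexose transporter genes, 1 fell, HXT4 (median -0.33, 4 lower when adjusted over the list alone, camera adjusted p = 0.00466, adjusted p = 0.162 with an estimated correlation). Camera called 6 lists higher and 8 lower in the average. In all, 1189 features passed in the average, 671 higher and 518 lower, 988 of them named, and 2422 had an unadjusted p under 0.05. The balance turned with median centring, to 586 higher and 664 lower, and was 688 and 512 on the deposited scale. The count was 675 and 710 without the first and the second untreated sgs1 null array, 546 and 588 without the MMS-treated ones, 587 and 478 without the untreated wild-type ones and 543 and 415 without the MMS-treated ones. All 1189 kept their direction in each of those 8 fits, but they were chosen on these same arrays, so the kept directions are no added support.

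**Figure D3:**
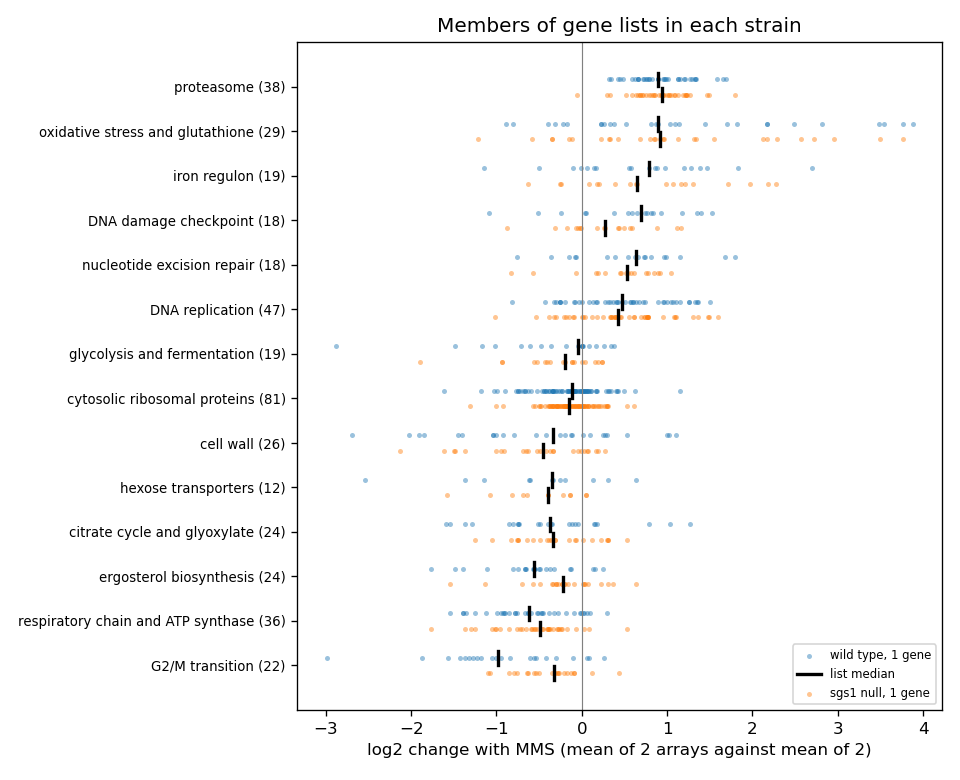
Log2 change with MMS of each member of 14 gene lists, with 1 point per gene, blue for wild type and orange for the sgs1 null strain, a bar at each list's median and the number of measured genes in parentheses. The proteasome medians were 0.90 and 0.94 and the respiratory chain medians -0.61 and -0.49, while the G2/M medians were -0.98 and -0.33.

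Some signs of RNA quality moved with MMS, and so with all of the gene groups above, and some with strain. The ratio of the 3' to the 5' ACT1 control probe sets was 1.78 and 1.84 in untreated and 2.23 and 2.07 in MMS-treated wild type, and 2.28 and 1.88 in untreated and 3.25 and 2.70 in the MMS-treated sgs1 null strain. The same ratio for SRB4 lay between 3.65 and 5.90 in wild type and between 5.96 and 8.04 in sgs1 null, higher with MMS in both strains. For SPT15 it did not move one way, being 2.37 and 2.99 in untreated and 2.69 and 2.80 in MMS-treated wild type, and 2.85 and 2.29 in untreated and 3.52 and 2.25 in MMS-treated sgs1 null. The 18S ribosomal RNA control probe sets read 437 and 245 on the second MMS-treated array of wild type and of the sgs1 null strain, and between 2046 and 8088 on the other 6 arrays. Without those 2 arrays, a setting chosen after the data were seen, limma called 0 features in the average over strains, 0 in wild type and 0 in the sgs1 null strain, with an unadjusted p under 0.05 for 2137, 1599 and 1313 features. That fit had fewer arrays, and in it the MMS effects of the strains still correlated at 0.719, against 0.730 with all arrays.

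Between the strains, few features passed the threshold. The ACT1 and SRB4 ratios of RNA quality were higher on the sgs1 null arrays within each treatment, and untreated the 18S probe sets read 2675 and 2217 in sgs1 null against 7713 and 3324 in wild type. Averaged over treatments, MEP2, an ammonium permease, was higher in the sgs1 null strain by 1.94 ± 0.12 (adjusted p = 0.0209), with intensities of 830.5 ± 57.2 in untreated wild type and 2259 ± 339 in the untreated null strain (SD, n = 2 each). PUT4, a proline permease, was higher by 1.58 ± 0.10 (adjusted p = 0.0209), COS8, of a subtelomeric gene family, by 2.12 ± 0.13 (adjusted p = 0.0209) and SHH3, a homolog of a succinate dehydrogenase subunit, by 1.93 ± 0.15 (adjusted p = 0.0406). The probe sets of COS8 may take signal from near-identical copies, which makes its value uncertain. YIR043C was higher by 1.39 ± 0.08, a bound because its untreated wild-type level was at the floor, and an uncertain value because its 2 probe sets disagreed, at 2.27 and 0.51. ARO10, a decarboxylase of amino acid breakdown, was lower by -1.58 ± 0.11 and OPT2, an oligopeptide transporter, by -1.12 ± 0.08 (adjusted p = 0.0323 for each). PUT1, the proline oxidase, singled out after its values were seen, was higher by 1.03 ± 0.07 (adjusted p = 0.0323). In all, 12 features passed, 9 higher and 3 lower, 8 of them named, and 856 had an unadjusted p under 0.05, against 382 for chance. With the rep mark of the labels as a replicate block 2 features passed, 1 of them among the 12, so most of the strain calls given here did not hold there. Of simulated 2-fold strain differences, 40% were recovered in the average, 16% untreated and 2% with MMS. Many differences of that size may thus not have been called, although these rates need not carry over to the real arrays. An unnamed probe set, also singled out after the values were seen, read 13072 to 16075 on the sgs1 null arrays and 3.1 to 11.2 on the wild-type arrays, which makes it at least 153-fold higher (adjusted p = 3.74e-06), and it alone passed without any 1 of the 8 arrays, so that each of those counts was 1. With low values left as they were, 30 features passed, 10 of them among the 12.

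Of 30 genes of methionine and sulfur assimilation, 0 passed over all genes between the strains averaged over treatments, and 12 were higher in the sgs1 null strain when adjusted over the list alone (median 0.43, camera adjusted p = 6.65e-10, adjusted p = 0.256 with an estimated correlation). Its members with the largest values were MET2 (1.81 ± 0.17, adjusted p = 0.0625), the S-methylmethionine permease gene MMP1 (1.62 ± 0.19), MET28 (1.55 ± 0.19) and SAM1 (1.34 ± 0.16), which did not pass. Of 83 ribosome biogenesis genes, 0 passed over all genes or adjusted over the list alone (median 0.20, 68 above 0, camera adjusted p = 6.44e-05, adjusted p = 0.556 with an estimated correlation). Of the 81 genes of the ribosomal protein list, 0 passed over all genes or adjusted over the list alone (median -0.12, 14 above 0, camera adjusted p = 1.42e-05, adjusted p = 0.556 with an estimated correlation). The ribosome biogenesis median was 0.13 without the second untreated wild-type array, and the ribosomal protein median -0.08 without the second MMS-treated sgs1 null or the first MMS-treated wild-type array. The list of mitosis exit genes was lower (16 genes, 0 past the threshold, 1 higher and 1 lower when adjusted over the list alone, median -0.24, camera adjusted p = 0.0148, adjusted p = 0.556 with an estimated correlation). That call was lost without the first untreated (adjusted p = 0.0874) or the first MMS-treated (median -0.15, adjusted p = 0.117) sgs1 null array or the second MMS-treated wild-type array (adjusted p = 0.105). The markers of the DNA damage response had values in this average of -0.02 ± 0.15 for RNR1, -0.01 ± 0.31 for RNR3, 0.08 ± 0.13 for RAD54, 0.07 ± 0.23 for MAG1, 0.29 ± 0.16 for HUG1, 0.14 ± 0.13 for RNR2, 0.14 ± 0.08 for RNR4, 0.11 ± 0.10 for DDR48 and -0.24 ± 0.14 for DDI1, none past the threshold. The averages of RNR3 and HUG1 joined values of opposite sign, 0.53 ± 0.44 and 0.84 ± 0.23 untreated and -0.55 ± 0.44 and -0.27 ± 0.23 with MMS.

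Without treatment, 2 features passed between the strains, neither of them named: the same unnamed probe set, at least 136-fold higher (adjusted p = 2.36e-05), and another that was lower (adjusted p = 0.0145). An unadjusted p under 0.05 was found for 805 features. The count was 1 without any 1 of the untreated arrays or of the MMS-treated sgs1 null arrays, and 13 with low values left as they were. The named genes with the smallest p did not pass: PUT4 (1.61 ± 0.14), COS8 (2.15 ± 0.18), SHH3 (2.29 ± 0.21), the spore wall gene SPS100 (3.12 ± 0.27), OPT2 (-1.16 ± 0.12) and DAN1 (-0.89 ± 0.08) had an adjusted p of 0.0858, as did YIR043C, at least 2.28-fold higher because untreated wild type was at the floor, with probe sets at 2.19 and 0.19. ADH2 (-1.30 ± 0.15), SFG1 (-2.00 ± 0.24) and ARO10 (-1.28 ± 0.16) an adjusted p of 0.126. The methionine and sulfur list was higher (0 past the threshold, 4 when adjusted over the list alone, median 0.25, camera adjusted p = 0.000557, adjusted p = 0.655 with an estimated correlation), with a median of 0.40 without the first untreated sgs1 null and 0.38 without the first untreated wild-type array. The ribosomal protein list was lower (0 past the threshold by either adjustment, 0 being also the count adjusted over the list alone, median -0.16, camera adjusted p = 0.000435, adjusted p = 0.655 with an estimated correlation), with -0.25 and -0.10 without the first and the second untreated sgs1 null array.

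With MMS, 1 feature passed between the strains, again the unnamed probe set, at least 172-fold higher, and 472 had an unadjusted p under 0.05. Among named genes, MEP2 (2.44 ± 0.17, adjusted p = 0.075), YIR043C (at least 3.00-fold, adjusted p = 0.075), the general amino acid permease gene GAP1 (1.89 ± 0.14, adjusted p = 0.085), ISF1 (1.43 ± 0.12) and COS8 (2.09 ± 0.18) had the smallest p in the upward direction. ARO10 (-1.87 ± 0.16), OPT2 (-1.09 ± 0.12), PPA2 (-0.86 ± 0.09), SNR50 (-0.81 ± 0.12) and HXT1 (-0.94 ± 0.14) had the smallest p downward, and none of these genes passed. The YIR043C value is a bound because 1 of its probe sets, at 0.82 against 2.35 for the other, lay at the floor in wild type. The methionine and sulfur list was higher in the sgs1 null strain (0 past the threshold, 11 when adjusted over the list alone, median 0.71, camera adjusted p = 7.78e-14, adjusted p = 0.14 with an estimated correlation). The ribosome biogenesis list was higher too (0 past the threshold by either adjustment, 0 adjusted over the list alone, median 0.26, camera adjusted p = 1.13e-06, adjusted p = 0.547 with an estimated correlation). That call was lost without the first MMS-treated sgs1 null array (adjusted p = 0.0649), and the median was 0.16 without that array or the second MMS-treated wild-type array. The G2/M list was higher (0 past the threshold, 3 when adjusted over the list alone, median 0.24, camera adjusted p = 6.99e-05, adjusted p = 0.528 with an estimated correlation). That call was lost without the second MMS-treated sgs1 null array (median 0.10, adjusted p = 0.173) or the first MMS-treated wild-type array (median 0.14, adjusted p = 0.0598). Its median was 0.50 without the first MMS-treated sgs1 null array and 0.37 without the second MMS-treated wild-type array. Camera called 9 lists higher and 2 lower with MMS, against 1 higher and 2 lower untreated. Apart from methionine and sulfur, each of the calls with MMS was lost without at least 1 of the arrays. Without 1 array the median with MMS ran from 0.04 to 0.44 for G1/S, and from 0.58 to 0.75 for methionine and sulfur. By limma, an unadjusted p under 0.05 was found for 472 features with MMS and 805 untreated. The list counts thus do not show that the strains differed more with MMS. Fry called 0 of the lists in either comparison, with an unadjusted p under 0.05 for 4 and 3, and in the average over treatments it kept 1 of camera's 5 calls. Across the 7641 features the strain differences untreated and with MMS were correlated (r = 0.381, rho = 0.290).

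Whether the MMS response itself differed between the strains was tested as an interaction. For no gene did limma find a difference (0 features, smallest adjusted p = 0.205), and 363 features had an unadjusted p under 0.05, against 382 for chance. The count was 0 with array weights and with a trended, robust prior too, and 1 with the floor at the 20th percentile. On the log2 scale the ACT1 ratio rose by 0.52 with MMS in sgs1 null and by 0.25 in wild type, while the SRB4 ratio rose by 0.33 and 0.44. The named genes with the smallest p were GAP1 (1.81 ± 0.20), DAN1 (0.94 ± 0.12), MYG1 (0.81 ± 0.12), ISF1 (1.08 ± 0.18) and SFG1 (2.00 ± 0.34) with a more positive change in the sgs1 null strain. ATR1 (-1.60 ± 0.22), HXT1 (-1.33 ± 0.20), SPS100 (-2.53 ± 0.38), MGM1 (-1.05 ± 0.16) and JJJ1 (-1.10 ± 0.17) had a more negative one, with adjusted p of 0.749 for GAP1 and 0.812 or above for the others. For RNR1 the difference was -0.06 ± 0.31, for RAD54 -0.46 ± 0.25, for RNR3 -1.08 ± 0.62 and for HUG1 -1.11 ± 0.33, none past the threshold. As a list, the G2/M genes fell less in the sgs1 null strain (22 genes, 0 past the threshold, 0 when adjusted over the list alone, median interaction 0.48, camera adjusted p = 0.000204, adjusted p = 0.449 with an estimated correlation). So did the ergosterol genes (24 genes, 0 past the threshold, 0 when adjusted over the list alone, median interaction 0.37, camera adjusted p = 0.000695, adjusted p = 0.449 with an estimated correlation). Fry called 0 lists for the interaction, with an unadjusted p under 0.05 for 1. The G2/M value was led by CHS2 (2.45 ± 0.57) and ALK1 (1.06 ± 0.24), neither past the threshold. Without the first MMS-treated sgs1 null and the first MMS-treated wild-type array the G2/M median was 0.80 and 0.28. The ergosterol median was 0.23 without the second untreated and 0.19 without the first MMS-treated wild-type array.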

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

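The tests of scaling and of RNA quality for the MMS average, the test of RNA quality for the strain difference and the test of members varying together for the G2/M list were chosen only after the result was seen.

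For 8 gene lists the change with MMS differed between the strains by camera's test of the interaction, and for none of them with an estimated correlation or by fry (0 lists, unadjusted p under 0.05 for 1). The G2/M transition list had a median interaction of 0.48 (-0.98 in wild type, -0.33 in sgs1 null). The ergosterol list had 0.37 (-0.56 against -0.22, camera adjusted p = 0.000695, adjusted p = 0.449 with an estimated correlation), and 0.23 without the second untreated and 0.19 without the first MMS-treated wild-type array. The G1/S list had 0.40 (-0.10 against 0.32, camera adjusted p = 0.000833, adjusted p = 0.741 with an estimated correlation). Its call was lost without the first untreated (adjusted p = 0.0529) or the second MMS-treated sgs1 null array (median 0.20, adjusted p = 0.0691), and the median was 0.77 without the first MMS-treated sgs1 null array and 0.66 without the second MMS-treated wild-type array. The mating and pheromone list had 0.34 (-0.26 against 0.11, camera adjusted p = 0.00342, adjusted p = 0.449 with an estimated correlation), and its call was lost without the dimmest 25% of features (adjusted p = 0.0628). The list of heat shock proteins and chaperones had -0.21 (0.03 against -0.07, camera adjusted p = 0.00786, adjusted p = 0.741 with an estimated correlation), with -0.40 on the arrays without the rep mark and 0.04 on those with it. Its call was lost without the first untreated (adjusted p = 0.0529) or the first MMS-treated sgs1 null array (median 0.14, adjusted p = 0.68), the first untreated (adjusted p = 0.0837) or the second MMS-treated wild-type array (median -0.07, adjusted p = 0.329), and under both other scalings (adjusted p = 0.249 with median centring and 0.187 on the deposited scale). The median was -0.44 without the second MMS-treated sgs1 null and -0.35 without the first MMS-treated wild-type array. The list of RNA polymerase I and III subunits had 0.27 (-0.21 against 0.14, camera adjusted p = 0.00936, adjusted p = 0.449 with an estimated correlation). Its call was lost without the first untreated (adjusted p = 0.0529) or the first MMS-treated sgs1 null array (median 0.13, adjusted p = 0.2) or the second MMS-treated wild-type array (median 0.18, adjusted p = 0.0822), and the median was 0.17 without the first untreated wild-type array. The amino acid biosynthesis list had 0.22 (0.03 against 0.17, camera adjusted p = 0.0155, adjusted p = 0.741 with an estimated correlation). This call was lost without the first untreated (adjusted p = 0.146) or the second MMS-treated sgs1 null array (adjusted p = 0.299), or the second untreated (median 0.12, adjusted p = 0.369) or the first MMS-treated wild-type array (median 0.15, adjusted p = 0.161). The methionine and sulfur list had 0.23 (-0.15 against 0.08, camera adjusted p = 0.0112, adjusted p = 0.488 with an estimated correlation), with 0.45 without and -0.06 with the rep mark. It lost its call without the first untreated (adjusted p = 0.721) or the first MMS-treated sgs1 null array (adjusted p = 0.0926) or the first untreated wild-type array (adjusted p = 0.0856). Its median was 0.41 without the second untreated sgs1 null array and 0.37 without the second MMS-treated sgs1 null or the second untreated wild-type array.

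The smaller fall of the G2/M genes in sgs1 null was weighed against technical explanations. Leaving out each of the 8 arrays kept the median interaction above 0, between 0.28 without the first MMS-treated wild-type and 0.80 without the first MMS-treated sgs1 null array. Median centring and the deposited scale left it at 0.33 or more. These values argue only against a single array or the scaling as the whole cause. The list was singled out on these same arrays, so the kept sign is no added support for a strain difference. The size of the median did depend on single arrays. Members of the list that vary together stay open, because the call was lost once their correlation was estimated (adjusted p = 0.449). A different effect of MMS on the cell cycle in the strains stays open too, as untested, and so does RNA quality, whose signs differed, the ACT1 ratio moving further with MMS in sgs1 null and the SRB4 ratio in wild type.

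For the MMS response averaged over strains, in a fit of 4 arrays against 4, the split by MMS called 1303 features. Of the 35 splits 1 gave as many, which is the smallest share these splits can give, and the highest of the others gave 5. This argues against a random grouping if the 8 arrays are separate units. The labels do not say that the arrays of a group came from separate cultures. If they did not, there are fewer units and splits, and this count cannot exclude chance. A difference peculiar to the rep-marked arrays is argued against by sign only, since 92.7% of the 858 features over 2-fold there kept their sign on the other arrays. The reverse share was lower, 85.7% of 976. Only 412 features were over 2-fold in the same direction on both sets of arrays, so the sizes of the changes agreed less than the signs. Scaling is argued against by the 1027 of 1189 features still called on the deposited scale and the 1051 with median centring. Lower RNA quality as the whole cause is argued against only as far as the ACT1 and SRB4 ratios measure it. Between the untreated strains these ratios moved by 0.795 and 1.17 of their shift with MMS in wild type. The 1189 features moved by 0.0817 of their MMS change (0.0475 without and 0.0932 with the rep mark). The control ratios were pooled over the marks. On the rep-marked arrays the ACT1 ratio was 1.84 in untreated wild type, 1.88 in untreated sgs1 null and 2.07 in MMS-treated wild type. It hardly differed between the untreated strains there, so by ACT1 those arrays alone cannot decide. The SRB4 ratio there was 4.82, 5.96 and 5.90 in the same order. The 1189 features were also chosen for their MMS change on these arrays, which can enlarge it. SPT15 was left out, its log2 ratio moving by -0.0587 between the untreated strains and 0.0451 with MMS in wild type. Ribosomal RNA was left out too, so its low reading on the rep-marked MMS arrays is not covered. Lower RNA quality as part of the cause and MMS itself cannot be told apart, because the median size of the change in sgs1 null, where the ACT1 ratio moved further and the SRB4 ratio less far, was 0.839 of that in wild type, a value that decides neither way.

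The strain difference averaged over treatments gave 5 features in a fit of 4 arrays against 4, and 2 of the 35 splits gave as many. The highest other split, with 1303, was the one by MMS, which points to a structure of the samples, and each remaining split gave 0. Because the MMS response alone made that split larger, the count does not tell whether chance can be excluded. The unnamed probe set lay far apart by strain on all 8 arrays, at 13072 to 16075 against 3.1 to 11.2. Lower RNA quality in sgs1 null as the whole cause is argued against only as far as the ACT1 and SRB4 ratios measure it. MMS moved these ratios by 1.15 and 0.836 of their strain difference but the 12 called features by -0.105 of theirs. SPT15 and ribosomal RNA were not part of this test, and RNA quality as part of the cause stays open.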

How the results depend on the processing

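The settings without a floor, with named genes only, without features at the floor on every array and without both rep-marked MMS arrays were chosen after seeing the data, and where no reason is given the cause was not tested. In the order MMS in wild type, MMS in sgs1 null, strain untreated, strain with MMS and interaction, MMS averaged and strain averaged, an adjusted p under 0.10 gave 1059, 592, 19, 9, 0, 1854 and 46 features, and an unadjusted p under 0.05 gave 1883, 1540, 805, 472, 363, 2422 and 856, by construction more. With low values left as they were, by the literal wording of the design or with no floor, MMS in sgs1 null gave 56, the strain difference untreated 13 and averaged 30, and SGS1 was -6.80 (adjusted p = 0.0055), a size set by readings below the floor. With the floor at the 20th percentile the strain difference untreated gave 6 and the interaction 1. Median centring gave 3 for the strain difference with MMS, and the deposited scale gave 4 untreated, 2 with MMS and 4 averaged. An offset of the 25th percentile gave 7, 5 and 27, with SGS1 at -1.50 (adjusted p = 0.0223). Without the dimmest 25% of features the strain counts were 10, 4 and 25. Without the dimmest 50%, which tests fewer features, MMS in wild type gave 265, the strain difference with MMS 4 and MMS averaged 744. A trended, robust prior gave 120 for MMS in sgs1 null and SGS1 at -2.46 (adjusted p = 0.0295). With only the 4 arrays compared, which leaves fewer samples, limma gave 0 for MMS in wild type (unadjusted p under 0.05 for 1741), 0 for MMS in sgs1 null (1318) and 1 for the strain difference untreated. With named genes only, which tests fewer features and leaves out the unnamed probe sets, the strain difference gave 0 untreated (unadjusted p under 0.05 for 523) and 0 with MMS (302), and SGS1 had an adjusted p of 0.0264 at -2.46. Without features at the floor on every array the strain counts were 6, 2 and 26, and SGS1 had an adjusted p of 0.0139 at -2.46. Without both rep-marked MMS arrays, which leaves fewer samples, the counts were 0 for MMS in wild type, 0 for MMS in sgs1 null, 1 for the strain difference untreated, 0 with MMS (unadjusted p under 0.05 for 414), 0 for MMS averaged and 1 for the strain difference averaged.

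With the rep mark as a replicate block, the counts were 935 for MMS in wild type, 496 in sgs1 null, 1847 averaged and 2 for the strain difference averaged, 1 of them among the 12. The deviations of arrays with the same mark correlated at 0.54, 0.20, 0.36, -0.08, 0.67 and -0.06 over the 6 pairs of groups. Not every pair was above 0.1, so the mark was not taken to pair the samples. Arrays of the 2 strains with the same treatment and mark correlated at 0.973 and 0.934 untreated and 0.975 and 0.974 with MMS. The 2 arrays of a group correlated at 0.966 and 0.954 in untreated and MMS-treated wild type and 0.961 and 0.952 in sgs1 null. In places the mark thus went with a larger difference than strain did. The reported fit leaves that difference in the spread. Without 1 array, the counts ran from 0 to 275 for MMS in wild type, 1 to 13 for MMS in sgs1 null, 1 to 2 for the strain difference untreated, 415 to 710 for MMS averaged, stayed at 1 for the strain difference with MMS and averaged and at 0 for the interaction, while SGS1 lay between -2.68 and -2.24 and the correlation of the MMS effects between 0.567 and 0.772.

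Directions turned for 5 named genes that had not passed the threshold. DDR48 in wild type was -0.0495 with median centring. HUG1 averaged over strains was 0.0707 on the deposited scale, and between -0.1669 and 0.1009 without 1 array, with 0.0145 without the second untreated sgs1 null array, 0.0692 without the second untreated wild-type array and 0.1009 without the first MMS-treated wild-type array. MLH2 in sgs1 null was -0.0077 without the second and 1.1109 without the first MMS-treated sgs1 null array, and -0.004 without both rep-marked MMS arrays. Between strains with MMS, RPC17 was 0.0568 without the first and -0.8913 without the second MMS-treated wild-type array, and PHM6 0.8859 and -0.0179. Of the 502 results for named genes, 459 kept their direction and side of the threshold with median centring, 457 on the deposited scale and 435 with low values left as they were, where 49 were no longer past it. With only the 4 arrays of the groups compared, 156 kept both and 135 were no longer past it. Without 1 array or without both rep-marked MMS arrays, fewer of the 502 kept both than under those other scalings. Of the 69 list calls, 64 held with median centring, 67 on the deposited scale and 33 with fry (10 of 12 for MMS in wild type, 10 of 16 in sgs1 null, 12 of 14 averaged, 1 of 5 for the strain difference averaged and 0 for the other contrasts). Without RPP1, a choice made after seeing the data, the ribosomal protein list kept all 6 calls. The signal near the floor limits dim genes.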

Other observations

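The lists of nitrogen-regulated and of oxygen-regulated genes were written after the values of a few members had been seen, and their members are named here for that reason. The test of the oxygen-regulated genes outside the fixed lists was chosen after the result was seen.

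Several lists that camera did not call with MMS averaged over strains held members that moved in that average. Of 35 genes of silencing and ageing, 6 rose and 1 fell (median 0.23, 7 higher and 3 lower when adjusted over the list alone, camera adjusted p = 0.07). SIR1, a silencing protein, rose by 0.95 ± 0.06 and RAP1, which binds telomeres and silencers, by 1.00 ± 0.17. In the sgs1 null strain camera did call this list, with 1 member higher and 1 lower (median 0.22, 6 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.0299, adjusted p = 0.192 with an estimated correlation). It lost that call without the first untreated (adjusted p = 0.183), the first MMS-treated (adjusted p = 0.0602) or the second MMS-treated sgs1 null array (adjusted p = 0.07). Of 5 histone genes, HTB2 alone fell (median -0.56, 1 lower when adjusted over the list alone, camera adjusted p = 0.086). Of 23 G1/S genes, 4 rose and 3 fell (median 0.03, 4 in each direction when adjusted over the list alone, camera adjusted p = 0.658), with CDC21, thymidylate synthase, rising by 0.84 ± 0.10 and the repressor gene YOX1 falling by 2.06 ± 0.30. Of 67 amino acid biosynthesis genes, 8 rose and 7 fell (median 0.10, camera adjusted p = 0.511, 9 higher and 8 lower when adjusted over the list alone), with ARG3 at 1.15 ± 0.14 and GLT1 at -1.14 ± 0.15.

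Of 18 multidrug transporter genes and their regulators, 5 rose (5 when adjusted over the list alone), among them FLR1 (2.39 ± 0.16) and YCF1 (1.81 ± 0.09), while the list's median was -0.24 and its mean 0.30 (camera adjusted p = 0.826). In the phosphate regulon, 2 of 13 genes rose and 2 fell (median 0.31, camera adjusted p = 0.311, 4 higher and 3 lower when adjusted over the list alone), with the transporter gene PHO84 at 0.63 ± 0.07 and the acid phosphatase gene PHO5 at -1.45 ± 0.13. Of 26 heat shock and chaperone genes, 1 rose (median 0.06, camera adjusted p = 0.699, 1 when adjusted over the list alone). Between strains averaged over treatments, the 35 silencing and ageing genes had a median of -0.04 with 0 past the threshold (1 lower when adjusted over the list alone, camera adjusted p = 0.324). The respiratory chain list had a median of 0.11 there (0 past the threshold, camera adjusted p = 0.00866, adjusted p = 0.556 with an estimated correlation), which turned to -0.01 with median centring (adjusted p = 0.32), and its call was lost without the first untreated sgs1 null array (median 0.07, adjusted p = 0.183) or the first MMS-treated wild-type array (adjusted p = 0.0596).

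A hypothesis was that genes under nitrogen catabolite repression were higher in the sgs1 null strain as a group, after MEP2, PUT1, PUT4 and GAP1 had been seen to be. The prediction, written before the other members were examined, was that at most 2.5% of 10000 random lists matched on level would have a higher median. The median of the 28 other members was 0.09, at the percentile 97.12, so that 2.88% lay above it and the prediction failed. The p by camera, unadjusted, was 0.0432 and with an estimated correlation 0.12. Of these members, 20 were above and 8 below 0, and 0 passed the threshold in limma.

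Another hypothesis was that genes regulated by oxygen were lower with MMS as a group, after ANB1, HEM13, DAN1 and CYC7 had been seen to fall. The result of the cell wall list, which shares the TIR genes, was known when this list was written. The median of the 17 other members was -0.56, and 0 of the 10000 random lists matched on level had a median as low, a percentile of 0 for the oxygen-regulated genes. Of the 17, 14 were below 0 and 6 fell, among them AAC3 (-1.70 ± 0.17) and COX5B (-1.68 ± 0.26), and 6 belonged to fixed lists with known results, so that this percentile was in part known beforehand. The median was -0.37 on the arrays without and -0.70 on those with the rep mark, and the p by camera, unadjusted, was 0.000522 and with an estimated correlation 0.0681. The 11 members outside the fixed lists, of which 3 fell, had a median of -0.37 at the percentile 1.57, with an unadjusted camera p of 0.035 and 0.206 with an estimated correlation. A lower expression of oxygen-regulated genes may be part of the difference between the MMS and untreated cultures, as a hypothesis found and tested on the same arrays. Different aeration of the cultures was not tested and stays open, as does RNA quality as part of the cause, since its signs moved with MMS.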
